A study of Mus musculus with 18 samples.

How the data were processed

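RNA sequencing was deposited for 18 mouse libraries. The first 6 were wild-type brain at embryonic days 11, 12, 13, 14, 16 and 18, with 1 library per stage in the files, although the study's design text speaks of cortex in triplicate. Another 4 were primary neural stem cells, 2 with a scrambled and 2 with a Pex7 short hairpin RNA. The other 8 were labelled brain with PLAAT3-PEX11 overexpression or its control, in a first set (Ctrl1 and PLA1) and a set named for neurons (Neuron-ctrl and Neuron-PLA), with 2 libraries per group. RNA was extracted with Trizol and 2 ug of total RNA were used, per the labels' protocols. Reads were aligned with STAR 2.7.9a to mm10 and counted with HTSeq 0.6.0, per the submitters' processing notes.

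The 4 deposited tables held RPKM, per the values themselves, since no header named the unit. Each value multiplied by the merged exon length of the gene in GENCODE M21 and by a read total per library gave a whole number of reads, within 0.01, for 97.5% to 97.8% of nonzero values. Of 32941 genes per table, 31976 (97.1%) matched such a length, and 31457 gave reads in all libraries. The recovered read totals were 16147911 to 28104927 in the perturbation libraries and 41501880 to 54373317 in the stage libraries. Even read numbers made up 53.6% to 55.1% of the values in the stage libraries and 47.3% to 49.1% in the others. A symbol used by more than 1 gene occurred 152 times, and all sample columns were used. Poisson intervals of Pex7 were computed from the recovered reads.

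The design, fixed before the data were examined, planned count models for deposited raw counts. The unit was RPKM, so its fallback for normalised values was used, and on the recovered reads only limma-voom was run, as an alternative. The fallback was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(RPKM + 1), on genes with a mean of at least 1 RPKM, and Benjamini-Hochberg adjusted p under 0.05. Each treated pair was compared with its control pair within its own table. The developmental test was the slope on embryonic day over the 6 stages. The interaction of set and treatment had been planned only for raw counts. It was run on RPKM after the data had been seen, because both tables used the same exon lengths and the comparison is a difference of differences within tables. Each fit was tested on simulated data in which 200 genes were changed. The changed genes were drawn from those with more reads, and each gene varied independently of the others. For the slope, the simulated fold was that between the first and the last stage. Shifts shared by many genes, as between the scramble libraries, were not simulated, so the simulation does not describe them. The share recovered at a 1.5-fold and a 3-fold change was 11% and 79% for the knockdown (12130 genes), 20% and 86% for the first set (11330 genes), 5% and 57% for the neuron set (10890 genes), 0% and 51% for the developmental slope (12573 genes) and 8% and 59% for the interaction (11405 genes). The share of called genes that had not been changed was 3.23%, 1.85%, 1.59%, 3.77% and 6.94%.

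Gene lists were fixed in advance and tested with camera of limma at a preset correlation between genes of 0.01, with an estimated correlation and fry as alternatives. An estimated correlation rests on the few residual degrees of freedom of so few libraries, which leaves that setting little power. A list that it did not call is therefore not shown to be unchanged. The 39 lists covered ether lipid synthesis, peroxins, peroxisomal enzymes, PLAAT and phospholipid turnover, radial glia, intermediate progenitors, pan-neuronal, deep-layer and upper-layer neurons, synapse, DNA replication, mitosis, respiratory complex I, complexes II to V, mitochondrially encoded mRNAs, mitochondrial biogenesis, tricarboxylic acid cycle, glycolysis, fatty acid oxidation, cholesterol synthesis, fatty acid synthesis, integrated stress response, unfolded protein response, antioxidant genes, p53 targets, interferon response, Notch, Wnt, immediate early genes, autophagy and lysosome, and 9 other cell types (astrocytes, oligodendrocyte lineage, interneurons, Cajal-Retzius cells, microglia, endothelium, pericytes and meninges, erythroid cells, choroid plexus). Lists could share genes, as the radial glia and Notch lists share Hes1, Hes5 and Notch1, so they are not independent. Counts of called members are given over all genes tested and adjusted over the list alone.

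Genes were named by a rule fixed in advance. Targeted genes came first. Then came the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, leaving out clone and predicted names. From each list with a called member or an adjusted p under 0.05, up to 4 members of smallest adjusted p could be named. Where no gene passed, the 5 of smallest p were named as not passing. For the slope the same rule was used, with Pex7, Gnpat, Agps and Far1 in addition, and for the interaction 5 genes per direction. Some genes that the rule selects are not reported here.

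Alternatives planned in advance were median-ratio and upper-quartile scaling, no filter on low values, a mean of at least 5 CPM, limma-voom on the recovered reads (at least 10 reads in 2 libraries), limma treat against a fold of 1.2, a pseudocount of 0.1, a block for the replicate number, the rank order of the stages, and leaving out each library in turn. Chosen after the data had been seen were 1 fit of all 12 perturbation libraries on RPKM, removal of a trend with exon length and GC, the interaction on genes with a mean of at least 1 RPKM in each set, and leaving libraries out of the correlations between comparisons. For the slope, the fold of 1.2 was per embryonic day. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.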

Results

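Gene expression was measured by RNA sequencing in 18 mouse libraries from a study of peroxisomes and ether lipids in the developing cortex. The stages, embryonic days 11, 12, 13, 14, 16 and 18, had 1 library each. The other 12 libraries formed 3 comparisons of 2 libraries against 2. They compared knockdown of Pex7 with a scrambled control in primary neural stem cells, and PLAAT3-PEX11 overexpression with a control in a first brain set (Ctrl1, PLA1) and in a set named for neurons (Neuron-ctrl, Neuron-PLA). The labels give brain as the source of both overexpression sets and do not say how the neurons were obtained. Values were RPKM per gene and library. The read totals behind them lay between 16147911 and 28104927 in the 12 perturbation libraries and between 41501880 and 54373317 in the stages. No label says that replicates came from separate animals or cultures, so p-values of single genes measure only the spread between these libraries, which may be technical. The camera p-values at the preset correlation set the members of a list against all other genes. They treat genes as nearly independent, so their small values do not measure the spread between libraries. Log2 changes are on the log2(RPKM + 1) scale, which understates the change of low genes, and RPKM was normalised within each library, so levels are compared within a table.

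The first comparison asked what follows when Pex7 is lowered in neural stem cells. Pex7 encodes the receptor that brings proteins with a type 2 peroxisomal signal, among them the ether lipid enzyme Agps, into peroxisomes. Pex7 (ENSMUSG00000020003; mm10 chromosome 10, 19853900 to 19907689, minus strand) stood at 1.19 and 1.22 RPKM in the scramble libraries, from 247 and 270 reads. In the Pex7sh libraries it stood at 0.500 and 0.669 RPKM, from 109 and 151 reads. The mean fell to 0.487 of the scramble level, with an SD of 0.0207 RPKM in the scramble pair and 0.119 RPKM in the Pex7sh pair (n = 2 each). The 95% Poisson intervals, which cover counting error only, were 1.04 to 1.34 and 1.08 to 1.37 RPKM in the scramble libraries and 0.411 to 0.604 and 0.567 to 0.785 RPKM in the Pex7sh libraries, and did not overlap between groups. With a mean under 1 RPKM, Pex7 lay outside the genes tested. In the unfiltered limma fit its log2 change was -0.48 (SE 0.11, unadjusted p = 0.0113), which did not pass the adjustment over all genes. In limma-voom on the recovered reads the log2 change was -1.05 (SE 0.19, unadjusted p = 0.00106), which did not pass either.

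No gene passed the test after the knockdown. Of 12482 genes tested with limma, 0 had an adjusted p under 0.05, and limma-voom also called 0 genes. At an unadjusted p under 0.05 there were 184 genes, against 624 expected by chance, and 145 in limma-voom. The 5 genes with the smallest p, named as not passing, were small RNAs: Mir99b (-1.37), Gm24564 (1.23), Mir7087 (-1.77), Mir3569 (-2.26) and Gm24144 (-1.44), with adjusted p from 0.218 upward. These rested on only 0 to 14 reads per library. None of the 9 measured ether lipid genes passed (median 0.05, SD 0.12, camera adjusted p = 0.323), nor did any of 14 peroxins (median -0.04, SD 0.08, adjusted p = 0.323) or 27 peroxisomal enzymes and transporters (median 0.01, mean -0.02, SD 0.12, adjusted p = 0.872). Of 38 gene lists, camera called 2. Nuclear-encoded complex I genes had a median change of 0.03 (SD 0.07, 25 of 35 members positive, 0 called, 0 adjusted over the list alone; adjusted p = 0.0295, and adjusted p = 0.947 with an estimated correlation), with Ndufs6 at 0.20 and Ndufa1 at 0.19. The p53 target and apoptosis list had a median of 0.05 (SD 0.08, 15 of 18 positive, 0 called, 0 adjusted over the list alone; adjusted p = 0.0416, and adjusted p = 0.947 with an estimated correlation), with Ccng1 at 0.18 and Mdm2 at 0.17. The complex I call was lost without scramble library 1 (adjusted p = 0.0558), scramble library 2 (0.134) or Pex7sh library 1 (0.555). The p53 call was lost without scramble library 1 (0.628), Pex7sh library 1 (0.144) or Pex7sh library 2 (0.199). Both were lost with fry (0.973) and with the exon length and GC trend removed (0.0512).

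The spread of this comparison came mainly from the scramble pair. Across genes, the scramble libraries correlated at r = 0.978, the Pex7sh libraries at 0.992, and libraries of different groups at 0.988 to 0.989. Over 8061 coding genes at 5 RPKM or more, the SD of the log2 difference was 0.258 between the scramble libraries, 0.0988 between the Pex7sh libraries and 0.0819 between the group means. Means of 2 libraries differ less than single libraries by construction, so the last value is not like the other ones. All 25 mitosis genes were higher in scramble library 1 than in scramble library 2 (median 0.78, SD 0.12), as were all 26 DNA replication genes (median 0.63, SD 0.14) and 16 of 18 radial glia markers (median 0.43, SD 0.26). All 17 pan-neuronal markers were lower in scramble library 1 (median -0.41, SD 0.14), as were all 24 synapse genes (median -0.31, SD 0.22). Without scramble library 1, 2324 genes had an unadjusted p under 0.05, and without scramble library 2 there were 2599, with 0 called in each case. The lists called numbered 12 without scramble library 1 and 11 without scramble library 2, against 1 without Pex7sh library 1 and 1 without Pex7sh library 2.

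**Figure D1:**
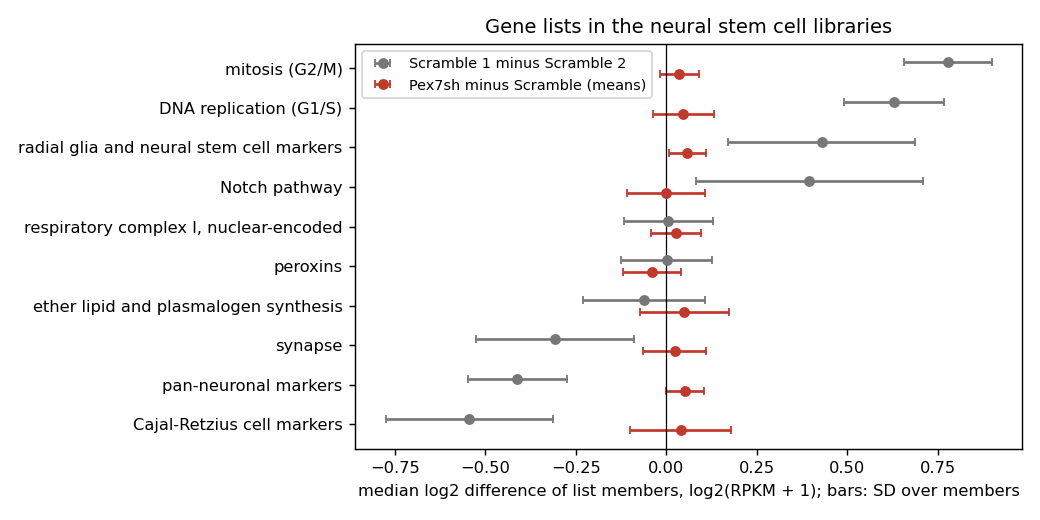
Median log2 difference of the members of 10 gene lists, on the log2(RPKM + 1) scale, between scramble library 1 and scramble library 2 (grey) and between the Pex7sh and scramble means (red); bars are the SD over members. Mitosis genes differed by a median of 0.78 between the scramble libraries and by 0.04 between the group means. Means of 2 libraries differ less than single libraries by construction.

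In the first overexpression set, PLA1 against Ctrl1, the lists that rose included interferon-response, stress-response and cell-cycle genes, and those that fell included neuronal, microglial and mitochondrially encoded genes. These calls used the preset correlation between genes, and with an estimated correlation none of the lists was called, with adjusted p of 0.188 or more. With 2 libraries per group that setting had little power, so the missing calls do not show that these lists were unchanged. Plaat3 was checked first. Plaat3 (ENSMUSG00000060675; mm10 chromosome 19, 7557459 to 7588545, plus strand), a phospholipase and acyltransferase gene, stood at 0.413 and 0.431 RPKM in Ctrl1 and 31.4 and 29.1 RPKM in PLA1, a log2 change of 4.46 (SE 0.13). Its adjusted p was 9.53e-06 in limma. The labels do not say which PEX11 sequence was used, and reads of Plaat3 from a construct and from the mouse gene cannot be separated in these values. Of 11623 genes tested, 1900 rose and 1538 fell, of which 251 and 196 changed at least 2-fold.

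Interferon-response genes rose most. Of 23 measured, 22 rose and 0 fell, and 22 rose adjusted over the list alone (median 1.46, SD 0.63; camera adjusted p = 5.45e-16, and adjusted p = 0.188 with an estimated correlation). Ifi44 rose from 12.2 ± 1.07 to 78.2 ± 4.07 RPKM (2.58), Ifit1 by 2.14, Oasl2 by 2.07 and Usp18, which encodes a protease that removes ISG15, by 1.68. Outside the list, Gbp6, an interferon-induced GTPase, rose by 2.38 and Parp12 by 2.34. Microglia and macrophage markers moved the other way. Of 12 measured, 9 fell, and 10 adjusted over the list alone (median -0.99, SD 0.39; adjusted p = 1.3e-07, and adjusted p = 0.267 with an estimated correlation), with Csf1r at -1.52, C1qb at -1.26 and C1qa at -1.15. Integrated stress response and amino acid synthesis genes also rose, 19 of 21 over all genes and 21 adjusted over the list alone (median 0.96, SD 0.54; adjusted p = 5.23e-13, and adjusted p = 0.188 with an estimated correlation). Trib3, a target of the transcription factor ATF4, rose by 2.28, Sesn2 by 2.00, the asparagine synthetase Asns by 1.71 and the glutathione-degrading enzyme Chac1 by 1.56. The endoplasmic reticulum unfolded protein response list was not called (3 rose and 1 fell of 18, adjusted p = 0.0679), with Herpud1 at 0.71 and Hspa5 at 0.48.

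Cell-cycle and progenitor genes rose in the same libraries. Mitosis genes rose for 22 of 25 members, and 25 adjusted over the list alone (median 0.65, SD 0.18; adjusted p = 1.7e-11, and adjusted p = 0.188 with an estimated correlation), with Aurkb at 0.84, Plk1 at 0.84 and Top2a at 0.76. DNA replication genes rose for 21 of 26, and 24 adjusted over the list alone (median 0.62, SD 0.24; adjusted p = 4.58e-10, and adjusted p = 0.321 with an estimated correlation), with Cdc6 at 1.02 and Mcm3 at 0.88. Of 18 radial glia and neural stem cell markers, 9 rose and 1 fell, and 11 and 1 adjusted over the list alone (median 0.35, SD 0.45; adjusted p = 0.00103, and adjusted p = 0.321 with an estimated correlation). Tnc rose by 1.40, the glutamate transporter Slc1a3 by 1.08 and Hes1 by 1.04, while Fabp7 fell by 0.32. Notch pathway genes rose for 8 of 13, and 9 adjusted over the list alone (median 0.65, SD 0.58; adjusted p = 0.00171, and adjusted p = 0.321 with an estimated correlation), with the ligand Jag1 at 1.98. This list shares Hes1, Hes5 and Notch1 with the radial glia list. Intermediate progenitor markers were not called (2 rose and 1 fell of 10, adjusted p = 0.652). Fgf15, a growth factor of the embryonic brain, rose from 1.85 ± 0.305 to 61.2 ± 3.79 RPKM (4.45), Hhip by 2.82 and Gli1 by 2.38, both targets of Hedgehog signalling, and the immediate early gene Egr1 by 2.62.

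Neuronal genes fell. Pan-neuronal markers fell for 9 of 17, and 10 adjusted over the list alone (median -0.48, SD 0.48; adjusted p = 6.63e-08, and adjusted p = 0.249 with an estimated correlation). Mapt, which encodes tau, fell from 75.9 ± 0.714 to 25.7 ± 0.682 RPKM (-1.53), Stmn2 by 1.48 and the tubulin gene Tubb3 by 1.27. Deep-layer projection neuron markers fell for 5 of 8, and 6 adjusted over the list alone (median -0.62, SD 0.27; adjusted p = 0.000248, and adjusted p = 0.321 with an estimated correlation), with Fezf2 at -0.90 and Bcl11b at -0.87. Synapse genes fell for 8 of 22, and 8 adjusted over the list alone (median -0.23, SD 0.47; adjusted p = 0.000937, and adjusted p = 0.321 with an estimated correlation), with Camk2b at -1.31 and Cplx1 at -1.30. Upper-layer markers were not called (1 rose and 2 fell of 11, adjusted p = 0.312), with Rorb at -1.19 and Cux1 at 0.41. Other cell types moved with these genes. Interneuron and ventral forebrain markers fell for 4 of 8 and rose for 1, and 5 and 1 adjusted over the list alone (median -0.54, SD 0.73; adjusted p = 0.0192, and adjusted p = 0.463 with an estimated correlation), with Dlx1 at -1.20. Astrocyte markers fell for 3 of 6 and rose for 1, and 3 and 1 adjusted over the list alone (median -0.58, SD 0.72; adjusted p = 0.0461, and adjusted p = 0.34 with an estimated correlation), with Apoe at -1.46 and Gja1 at 0.58. Cajal-Retzius markers fell for 2 of 5, and 2 adjusted over the list alone (median -0.32, SD 0.43; adjusted p = 0.0314, and adjusted p = 0.337 with an estimated correlation), with Nhlh2 at -1.08. The interneuron and astrocyte calls were lost without PLA1 library 1 (adjusted p = 0.0792 for each), and the Cajal-Retzius call without PLA1 library 1 (0.143) or Ctrl1 library 2 (0.0672). Further large falls were in Mc4r (-1.90), Golga7b (-1.77), Lrrc4c (-1.76), Cck (-1.75), Txnip (-1.75), Coa3 (-1.74), Ngfr (-1.71), Jph3 (-1.71), Nap1l2 (-1.71) and Ankrd34a (-1.69).

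Mitochondrially encoded, respiratory chain and lysosomal genes fell as well. Mitochondrially encoded mRNAs fell for 10 of 12, and 12 adjusted over the list alone (median -1.06, SD 0.32; adjusted p = 7.12e-10, and adjusted p = 0.267 with an estimated correlation). ND4 fell from 341 ± 16.6 to 131 ± 11.4 RPKM (-1.37), ND5 by 1.35 and ATP6 by 1.29. Nuclear genes of complexes II to V fell for 15 of 37, and 20 fell and 1 rose adjusted over the list alone (median -0.30, SD 0.30; adjusted p = 4.37e-06, and adjusted p = 0.51 with an estimated correlation), with Cox6b1 at -0.98 and Cox7a2 at -0.63. Nuclear complex I genes fell for 10 of 34 and rose for 1, and the same counts held adjusted over the list alone (median -0.20, SD 0.25; adjusted p = 0.00041, and adjusted p = 0.51 with an estimated correlation), with Ndufa5 at -0.70. The complex I call was lost with the exon length and GC trend removed (median -0.02, camera adjusted p = 0.0573) and with fry (adjusted p = 0.175). That of complexes II to V was lost with fry (adjusted p = 0.151). Autophagy and lysosome genes fell for 10 of 23, and 10 adjusted over the list alone (median -0.24, SD 0.40; adjusted p = 4e-05, and adjusted p = 0.267 with an estimated correlation), with Map1lc3a at -1.10. Glycolysis genes fell for 6 of 23 and rose for 1, and 6 and 1 adjusted over the list alone (median -0.10, SD 0.37; adjusted p = 0.0266, and adjusted p = 0.321 with an estimated correlation), with Eno2 at -0.85 and Hk2 at 0.86, a call lost without PLA1 library 2 (adjusted p = 0.0557).

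Other mitochondrial and peroxisomal lists were not called in the first set. Of 23 mitochondrial biogenesis and dynamics genes 2 rose and 1 fell (median 0.18, SD 0.32, adjusted p = 0.65), of 20 tricarboxylic acid cycle genes 1 rose and 1 fell (median -0.04, SD 0.20, adjusted p = 0.325), and of 17 fatty acid oxidation genes 0 changed (median 0.04, SD 0.19, adjusted p = 0.961). Ether lipid synthesis genes did not change by this test (0 of 9, median 0.05, SD 0.23, adjusted p = 0.962). Among 15 peroxins, 1 rose and 1 fell, Pex5 (-0.49), with an adjusted p of 0.678 for the list. Of 26 peroxisomal enzymes and transporters 2 rose and 4 fell (adjusted p = 0.191), with Idh1 at -0.95. Of 13 genes of the PLAAT family and phospholipid turnover 1 rose and 3 fell (median -0.07, mean 0.21, adjusted p = 0.501), with Plaat3 itself as the rise and Tmem86a, a lysoplasmalogenase gene, at -1.02.

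Of the 36 lists tested in the first set, 18 were called by camera and 0 with an estimated correlation. With the exon length and GC trend removed the calls of complex I (adjusted p = 0.0573), glycolysis (0.0573) and astrocyte markers (0.0618) were lost. The median of complex I went from -0.20 to -0.02 there, so most of its fall went with that trend, while glycolysis went from -0.10 to -0.07, astrocyte markers from -0.58 to -0.47 and complexes II to V, still called, from -0.30 to -0.19. In addition, fry did not call complex I (0.175) or complexes II to V (0.151). The count of changed genes was 1575 without Ctrl1 library 1 and 2048 without PLA1 library 2, against 3438 with all 4 libraries. The share of rises among called genes turned from 55.3% to 47.2% with median-ratio scaling (1571 rose, 1757 fell) and 40.3% with upper-quartile scaling (1327 rose, 1968 fell), while no called list changed the sign of its median. Glycolysis moved to -0.16 and -0.21 under these scalings, and complex I to -0.30 with upper-quartile scaling.

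**Figure D2:**
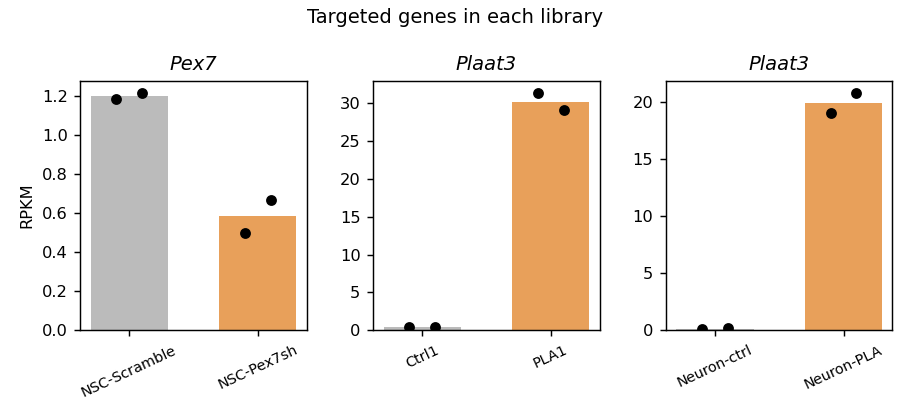
RPKM of Pex7 and Plaat3 in each library (points) with group means (bars), for the knockdown and both overexpression sets, with a separate axis per panel. Every treated library lay on the same side of both of its controls, with Pex7 at 0.500 and 0.669 RPKM against 1.19 and 1.22.

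In the neuron set, Neuron-PLA against Neuron-ctrl, Plaat3 rose again and fewer other genes changed, and lists of markers of interneurons and several non-neuronal cell types fell. These list calls used the preset correlation, and with an estimated correlation none was called, with adjusted p of 0.44 or more. That setting had little power here too. Plaat3 stood at 0.0699 and 0.230 RPKM in Neuron-ctrl and 19.0 and 20.8 RPKM in Neuron-PLA (log2 change 4.19, SE 0.17, limma adjusted p = 0.000202). Of 11179 genes tested, 42 rose and 56 fell, and 1976 had an unadjusted p under 0.05. Other rises were in Smtnl2 (1.63), Cwc22 (1.30), a splicing factor gene whose copy number differs between mouse strains, the nuclear receptor gene Nr4a2 (1.06), Bcl2l2 (1.03), a survival gene of the Bcl2 family, Nvl (0.98), Pusl1 (0.94) and the long noncoding RNA Miat (0.93). Rps2 (1.32) and Rpsa-ps10 (-1.72) also passed, but both share reads with near-identical copies and are uncertain. The largest fall was in Cldn5, an endothelial tight junction gene, from 17.7 ± 0.389 to 1.45 ± 0.276 RPKM (-2.94, SE 0.15). Too few endothelial markers reached a mean of 1 RPKM for that list to be tested here, so Cldn5 alone does not show a loss of endothelial cells. Rgcc (-1.66), the globin genes Hbb-b1 (-1.49) and Hba-a1 (-1.32), which have near-identical copies, Rpp25 (-1.43), the microglial gene Tmem119 (-1.43), the pericyte gene Rgs5 (-1.31), Cavin1 (-1.25) and Car2 (-1.20) also fell.

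Markers of several cell types fell as lists in the neuron set. Interneuron and ventral forebrain markers fell for 6 of 12, and 8 adjusted over the list alone (median -0.74, SD 0.36; camera adjusted p = 1.09e-08, and adjusted p = 0.44 with an estimated correlation), with Dlx1 at -0.94, Sst, which encodes somatostatin, at -0.94, and Gad2, an enzyme of GABA synthesis, at -0.82. Astrocyte markers fell for 3 of 7, and 5 adjusted over the list alone (median -0.76, SD 0.42; adjusted p = 2.19e-05, and adjusted p = 0.44 with an estimated correlation), with Sparcl1 at -0.86 and Apoe at -0.80. Radial glia markers fell for 2 of 15, and 8 fell and 1 rose adjusted over the list alone (median -0.49, SD 0.42; adjusted p = 1.88e-05, and adjusted p = 0.44 with an estimated correlation), with Fabp7 at -0.91 and Hes5 at -0.76. Microglia markers fell for 2 of 11, and 5 adjusted over the list alone (median -0.43, SD 0.41; adjusted p = 4.9e-05, and adjusted p = 0.451 with an estimated correlation), with C1qb at -0.88. Erythroid markers fell for 2 of 4, and 3 adjusted over the list alone (median -0.92, SD 0.52; adjusted p = 0.000389, and adjusted p = 0.44 with an estimated correlation). Pericyte, meningeal and fibroblast markers fell for 1 of 2, and 2 adjusted over the list alone (median -0.93, SD 0.53; adjusted p = 0.012, and adjusted p = 0.451 with an estimated correlation). Upper-layer neuron markers rose for 1 of 11, and 2 adjusted over the list alone (median 0.22, SD 0.16; adjusted p = 0.0029, and adjusted p = 0.451 with an estimated correlation), a call lost without Neuron-ctrl library 1 (adjusted p = 0.0524). Oligodendrocyte lineage (0 of 6 called, median -0.07, adjusted p = 0.624), Cajal-Retzius (0 of 3, median -0.06, adjusted p = 0.302) and intermediate progenitor markers (0 of 7, median -0.10, adjusted p = 0.38) were not called. Pan-neuronal markers (0 of 17 called, median 0.06, adjusted p = 0.168) and deep-layer markers (1 rose of 8, median -0.08, mean 0.04, adjusted p = 0.854) were not called as lists. Among 22 synapse genes only Gria2 (0.68), a glutamate receptor gene, passed (list adjusted p = 0.425).

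Nuclear genes of the respiratory chain had lower values in Neuron-PLA. Complex I genes were negative for 33 of 35, of which 1 fell over all genes tested and 18 adjusted over the list alone (median -0.38, SD 0.23; adjusted p = 8.58e-11, and adjusted p = 0.451 with an estimated correlation), with Ndufa12 at -0.78. Genes of complexes II to V were negative for 37 of 38, of which 0 fell over all genes and 14 adjusted over the list alone (median -0.31, SD 0.16; adjusted p = 3.27e-10, and adjusted p = 0.482 with an estimated correlation). Mitochondrially encoded mRNAs fell for 1 of 11, ND1 (-0.34), and 4 adjusted over the list alone (median -0.16, mean -0.02, SD 0.42; adjusted p = 0.0162, and adjusted p = 0.482 with an estimated correlation). Of 20 antioxidant and NRF2 target genes 1 fell, Ftl1 (-0.29), and 5 adjusted over the list alone (median -0.19, SD 0.27; adjusted p = 0.000377, and adjusted p = 0.451 with an estimated correlation). Mitosis genes had a median of -0.35 (SD 0.23; 0 of 24 called, 4 adjusted over the list alone; adjusted p = 0.000266, and adjusted p = 0.44 with an estimated correlation). DNA replication genes had a median of -0.22 (SD 0.22; 0 of 25 called, 0 adjusted over the list alone; adjusted p = 0.0221, and adjusted p = 0.451 with an estimated correlation). Glycolysis genes had a median of -0.14 (SD 0.27; 0 of 22 called, 1 higher and 1 lower adjusted over the list alone; adjusted p = 0.0221, and adjusted p = 0.451 with an estimated correlation). Immediate early genes had a median of -0.19 (SD 0.19; 0 of 8 called, 2 adjusted over the list alone; adjusted p = 0.0299, and adjusted p = 0.451 with an estimated correlation). Integrated stress response genes fell for 1 of 16, the serine synthesis gene Phgdh (-0.66), and 4 fell and 1 rose adjusted over the list alone (median -0.20, SD 0.36; adjusted p = 0.0333, and adjusted p = 0.451 with an estimated correlation). The PLAAT and phospholipid turnover list rose for 1 of 11, Plaat3 itself, and 3 adjusted over the list alone (median 0.14, SD 1.29; adjusted p = 0.0396, and adjusted p = 0.451 with an estimated correlation). Because the list holds the overexpressed gene, its call is partly built in, and it was not tested without Plaat3. Only 6 interferon-response genes reached a mean of 1 RPKM, and they were not called (0 changed, 1 higher adjusted over the list alone, median -0.26, mean -0.06, SD 0.52, adjusted p = 0.854), nor were ether lipid genes (0 of 8, median 0.04, SD 0.13, adjusted p = 0.657) or peroxins (1 rose of 14, adjusted p = 0.944).

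Of the 37 lists tested in the neuron set, 17 were called by camera and 0 with an estimated correlation. Calls of DNA replication (0.206), mitochondrially encoded (0.166), glycolysis (0.0721), stress response (0.0549) and immediate early genes (0.167) were lost without Neuron-ctrl library 1, those of DNA replication (0.0904), stress response (0.185), immediate early (0.0996) and PLAAT genes (0.185) without Neuron-PLA library 2, those of mitochondrially encoded (0.258) and PLAAT genes (0.235) without Neuron-PLA library 1, and that of PLAAT genes (0.0765) without Neuron-ctrl library 2, each value in brackets being the adjusted p. With the exon length and GC trend removed the calls of both lists that had risen, PLAAT (0.0536) and upper-layer genes (0.0770), were lost, as were those of mitochondrially encoded (0.573), stress response (0.104) and immediate early genes (0.104). Medians went from 0.14 to 0.07 for PLAAT, 0.22 to 0.07 for upper-layer, -0.16 to -0.05 for mitochondrially encoded, -0.20 to -0.13 for stress response and -0.19 to -0.14 for immediate early genes. With fry the calls of complex I (0.207), complexes II to V (0.233), mitochondrially encoded (0.296), DNA replication (0.167), antioxidant (0.158), upper-layer (0.0980), stress response (0.0980), immediate early (0.0918), glycolysis (0.0808) and microglia genes (0.0808) were lost. The gene count was 7 without Neuron-ctrl library 1, 11 without Neuron-ctrl library 2, 9 without Neuron-PLA library 1 and 163 without Neuron-PLA library 2, against 98 with all 4 libraries and 0 with no filter on low values, and the list count was 11 without Neuron-ctrl library 1.

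**Figure D3:**
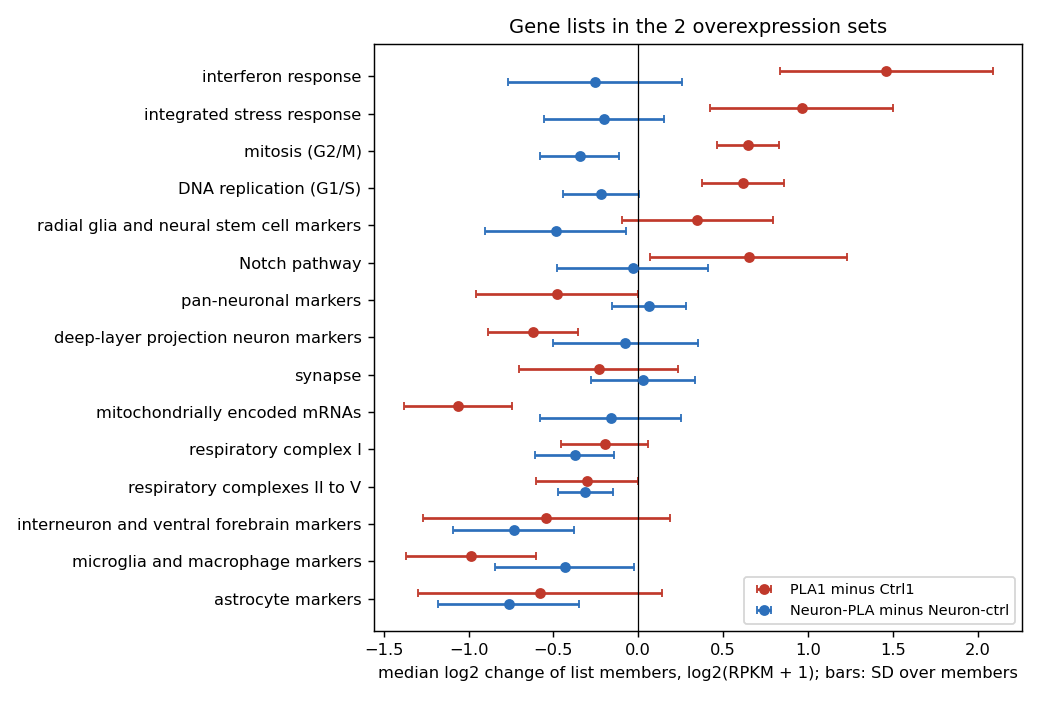
Median log2 change of the members of 15 gene lists, on the log2(RPKM + 1) scale, in the first set (red, PLA1 minus Ctrl1) and the neuron set (blue, Neuron-PLA minus Neuron-ctrl); bars are the SD over members. Interferon-response genes lay at 1.46 in the first set (23 members) and -0.26 in the neuron set (6 members).

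Whether the overexpression acted differently in the 2 sets was tested as the interaction of set and treatment over their 8 libraries. Of 11705 genes, 642 had a higher and 725 a lower log2 change in the neuron set than in the first set. That balance turned to 723 and 603 with median-ratio scaling and to 739 and 564 with upper-quartile scaling. The change was lower in the neuron set for integrated stress response genes, 15 of 18, and 17 adjusted over the list alone (median difference -1.31, SD 0.69; camera adjusted p = 4.41e-16, and 0.0108 with an estimated correlation), and for mitosis genes, 19 of 25, and 24 adjusted over the list alone (-0.98, SD 0.26; adjusted p = 2.38e-14, and 0.0108 with an estimated correlation). Pan-neuronal markers went the other way, with a higher change in the neuron set for 8 of 17, and 13 adjusted over the list alone (0.61, SD 0.47; adjusted p = 4.6e-11, and 0.0179 with an estimated correlation). Interferon-response genes were lower for 19 of 23, and 20 adjusted over the list alone (-1.46, SD 0.73; adjusted p = 4.41e-16, and 0.0108 with an estimated correlation), but 17 of the 23 had a mean under 1 RPKM in the neuron set, so the difference rests mainly on the first set. On genes with a mean of at least 1 RPKM in each set, a test added after the data had been seen, 4 of the remaining 6 were lower, and 4 adjusted over the list alone (-1.06, SD 0.90; adjusted p = 0.00874, and adjusted p = 0.148 with an estimated correlation). The other 3 lists kept their calls there under both settings, with an adjusted p of 0.0158, 0.0158 and 0.0238 with an estimated correlation, and radial glia markers, lower for 8 of 15, were also called under both (-0.66, SD 0.59; adjusted p = 9.24e-08, and 0.0340 with an estimated correlation). For Ifi44, with 0 RPKM in both Neuron-ctrl libraries, the difference of -2.45 turned to 1.62 in limma-voom. Single genes with the largest differences were Ngfr (2.58), Txnip (2.10), Eif2s3y (2.07), Mc4r (1.94) and Coa3 (1.90) in one direction, and Fgf15 (-4.39), Cldn5 (-2.92), Hhip (-2.86), Egr1 (-2.84) and Sesn2 (-2.84) in the other. Fgf15 and Hhip lay under 1 RPKM in all libraries of the neuron set, and Cldn5 in all libraries of the first set. Eif2s3y is Y-linked, and the Y-linked Ddx3y moved with it, at 9.07 and 9.54 RPKM in Ctrl1, 3.38 and 4.33 in PLA1, 6.48 and 6.55 in Neuron-ctrl and 11.7 and 11.6 in Neuron-PLA. Treated and control libraries thus differed in sex mix in both sets, in opposite directions. The sex mix cannot be separated from the treatment in either set or in the interaction. The count of genes was 636 without Ctrl1 library 1, 744 without Ctrl1 library 2, 848 without PLA1 library 2 and 890 without Neuron-ctrl library 2, against 1367 with all libraries. RPKM was scaled library by library in both tables, and the fit compares only differences taken within each table.

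The shared response of the perturbations was small. Across 10424 genes tested in both overexpression sets, their log2 changes correlated at r = 0.18, and genes are not independent replicates. In both sets 15 genes rose, against 5.85 expected from independent lists, and 20 fell, against 6.93. The 15 included Plaat3 itself, and Cwc22, Miat, Nvl and Bcl2l2. Genes that rose in the first set and fell in the neuron set numbered 8, against 7.50 expected, and 3 went the other way, against 5.4. The knockdown correlated with the first set at r = -0.05 over 10686 genes and with the neuron set at -0.10 over 10588 genes. Those values turned to 0.273 without scramble library 1 and to 0.0555 without scramble library 2. The knockdown and neuron set value was -0.170 without scramble library 1 and -0.0253 without Pex7sh library 1, and the knockdown and first set value was -0.324 without scramble library 2 and -0.0328 without Pex7sh library 2.

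The stage libraries describe how the same genes ran over normal development. With 1 library per stage no stage could be tested against another, and the test was of a straight line with embryonic day against the scatter around it. Gnpat (ENSMUSG00000031985; mm10 chromosome 8, 124863033 to 124890057), the acyltransferase that starts ether lipid synthesis, fell by 0.12 log2 units per day (SE 0.02, limma adjusted p = 0.00262), from 36.4 RPKM at day 11 to 18.6 RPKM at day 18. Agps (ENSMUSG00000042410; mm10 chromosome 2, 75832177 to 75931350), the next enzyme of the pathway, fell by 0.10 per day (SE 0.03, adjusted p = 0.0210), from 6.66 to 3.39 RPKM. Far1 (ENSMUSG00000030759; mm10 chromosome 7, 113513834 to 113571511), which makes the fatty alcohol, did not pass (-0.07, SE 0.03, adjusted p = 0.0652), nor did Pex7 (-0.01, SE 0.02, adjusted p = 0.865), with 1.37 RPKM at day 11 and 1.32 RPKM at day 18. Of 10 ether lipid genes 1 rose, Peds1 (0.07), which makes the vinyl ether bond of plasmalogens, and 3 fell, Gnpat, Agps and Chpt1 (-0.08), with the same counts adjusted over the list alone (camera adjusted p = 0.701 for the list). Of 16 peroxins 2 rose and 2 fell (adjusted p = 0.613), among them Pex2 (-0.16) and Pex13 (-0.10).

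Of 12921 genes, 2528 rose and 3300 fell with day. The largest slopes upward were in the synaptic genes Nrgn (0.81 per day) and Camk2b (0.67), Dync1i1 (0.66), the neuronal surface gene Thy1 (0.66), Rprml (0.63), Vsnl1 (0.61), Adap1 (0.60), Bcan (0.60) and Sparcl1 (0.60). The largest slopes downward were in the embryonic globin genes Hbb-y (-1.65), Hba-x (-1.22) and Hbb-bh1 (-0.92), the embryonic chromatin gene Hmga2 (-0.75), Crabp2 (-0.71), Fgf15 (-0.58) and the cell division genes Ube2c (-0.57), Spc24 (-0.56), Ccnb1 (-0.55) and Top2a (-0.54). Mitosis genes fell for 25 of 25 (25 adjusted over the list alone; adjusted p = 6.23e-13) and DNA replication genes for 25 of 26 (25 adjusted over the list alone; adjusted p = 2.91e-12), with medians of -0.49 and -0.36 per day. Synapse genes rose for 20 of 24 and fell for 1 (21 and 1 adjusted over the list alone; adjusted p = 8.08e-09), with Grin1 at 0.44 and Syn1 at 0.33, and pan-neuronal markers rose for 10 of 17 (10 adjusted over the list alone; adjusted p = 0.000256), with Mapt at 0.52 and Snap25 at 0.35. Notch pathway genes fell for 13 of 16 and rose for 1 (13 and 1 adjusted over the list alone; adjusted p = 0.00072), with Dll1 at -0.33 and Jag2 at 0.27. Radial glia markers fell for 11 of 18 and rose for 2 (12 and 3 adjusted over the list alone; adjusted p = 0.0349), with Sox2 at -0.33 and Prom1 at -0.36, and intermediate progenitor markers fell for 7 of 10 (7 adjusted over the list alone; adjusted p = 0.02), with Neurog1 at -0.54. With an estimated correlation, a setting with little power at 1 library per stage, each of these 7 lists had an adjusted p = 0.654.

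A further 6 lists followed the day, each also with an adjusted p = 0.654 with an estimated correlation. Mitochondrial fatty acid oxidation genes fell for 9 of 17 and rose for 1 (10 and 1 adjusted over the list alone; adjusted p = 0.0162), with Eci1 at -0.22. Mitochondrially encoded mRNAs rose for 5 of 13 (1 adjusted over the list alone; adjusted p = 0.0366), with a median of 0.07 per day, which was 0.15 with the exon length and GC trend removed, and ND3 at 0.17. Autophagy and lysosome genes rose for 10 of 23 and fell for 2 (11 and 2 adjusted over the list alone; adjusted p = 0.00983), with Map1lc3a at 0.26. Microglia markers rose for 7 of 10 (8 adjusted over the list alone; adjusted p = 0.00736), with Aif1 at 0.29. Astrocyte markers rose for 5 of 8 and fell for 1 (5 and 1 adjusted over the list alone; adjusted p = 0.0162), with Aldh1l1 at 0.41. Erythroid markers fell for 5 of 9 (6 adjusted over the list alone; adjusted p = 0.0278). Without the library of day 18 the calls of intermediate progenitor (adjusted p = 0.292), mitochondrially encoded (0.234), astrocyte (0.136) and erythroid genes (0.0912) were lost, as was the mitochondrially encoded call without day 11 (0.107) or with fry (0.131) and the intermediate progenitor call with fry (0.0687), and 2537 genes were called in place of 5828.

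**Figure D4:**
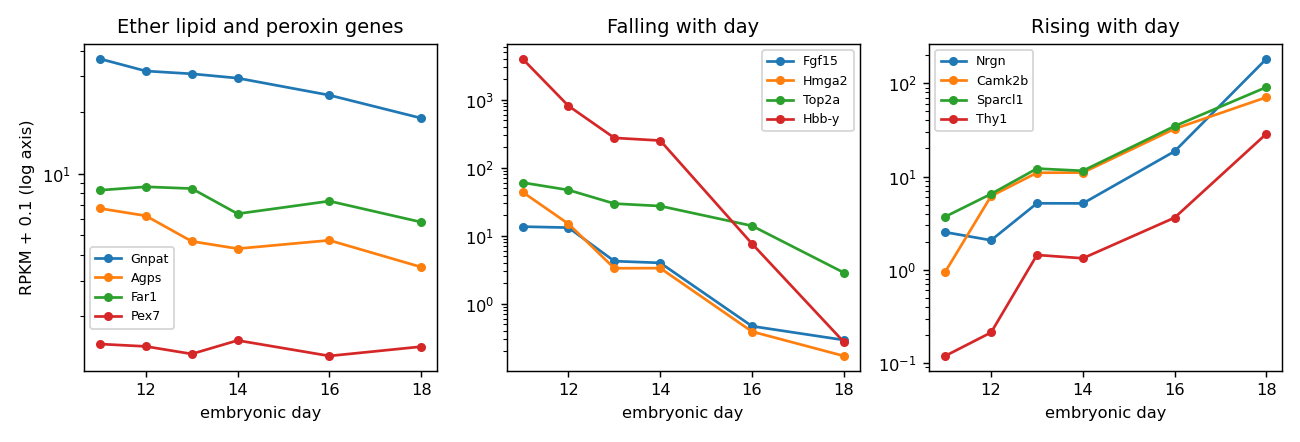
RPKM plus 0.1 on a log axis against embryonic day, 1 library per stage, for ether lipid and peroxin genes (left), genes with large downward slopes (middle) and genes with large upward slopes (right). Gnpat went from 36.4 to 18.6 RPKM between days 11 and 18, and Fgf15 fell while Nrgn rose.

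The first overexpression set ran against this course. Across 10627 genes, the log2 change in PLA1 correlated with the slope per day at r = -0.478. Of genes called in both, 1598 moved against their developmental direction and 181 with it. Among them 982 rose in PLA1 and fell with day, against 473 expected from independent lists, and 616 fell in PLA1 and rose with day, against 244. Both rises numbered 78, against 288 expected, and both falls 103, against 400. A shift of similar size lay between the 2 scramble libraries of the neural stem cells, which had the same treatment. Scramble library 1 minus scramble library 2 correlated with the slope at r = -0.562. Mitosis genes differed there by a median of 0.78, against 0.65 in PLA1. Such a shift can thus lie between libraries without a treatment, so these values alone do not tie it to the overexpression. The neuron set correlated with the slope at r = 0.113 over 10534 genes, with 21 genes in the same and 21 in the opposite direction, and at 0.0629 without day 11. The knockdown correlated at -0.00458 over 11512 genes, but at -0.460 without scramble library 1 and 0.426 without scramble library 2, and also moved to 0.0508 without Pex7sh library 1 and -0.0592 without Pex7sh library 2.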

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

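The difference between the 2 overexpression sets met the rule for a closer look, because the interaction of set and treatment was tested and passed for 1367 genes. Genes with a higher change in the neuron set were Ngfr (2.58), Txnip (2.10), the Y-linked Eif2s3y (2.07), Mc4r (1.94) and Coa3 (1.90). Genes with a lower change were Fgf15 (-4.39), Cldn5 (-2.92), Hhip (-2.86), Egr1 (-2.84) and Sesn2 (-2.84). Fgf15 and Hhip were under 1 RPKM throughout the neuron set and Cldn5 throughout the first set. Of the lists, 4 were called under both correlation settings, with median differences of -1.46 for interferon response, where 17 of 23 genes were under 1 RPKM in the neuron set, -1.31 for integrated stress response, -0.98 for mitosis and 0.61 for pan-neuronal markers. Another 13 lists passed only at the preset correlation, and each adjusted p that follows is from camera of limma with an estimated correlation. Lower in the neuron set were radial glia (-0.72, adjusted p = 0.0563), DNA replication (-0.73, adjusted p = 0.0589), Notch (-0.80, adjusted p = 0.164), Wnt targets (-0.59, adjusted p = 0.191), immediate early genes (-0.43, adjusted p = 0.154) and the unfolded protein response (-0.22, adjusted p = 0.157). Higher were mitochondrially encoded mRNAs (0.95, adjusted p = 0.0563), deep-layer (0.59, adjusted p = 0.191) and upper-layer markers (0.24, adjusted p = 0.329), synapse (0.52, adjusted p = 0.0954), autophagy and lysosome (0.25, adjusted p = 0.0589), microglia (0.40, adjusted p = 0.154) and cholesterol synthesis (0.093, adjusted p = 0.164).

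Some of these list calls were lost without 1 library, by adjusted p: upper-layer markers without PLA1 library 1 (0.0784), the unfolded protein response without PLA1 library 1 (0.0662) or Neuron-ctrl library 2 (0.0545), Wnt targets without Ctrl1 library 2 (0.0533), PLA1 library 1 (0.0907), Neuron-ctrl library 2 (0.0594) or Neuron-PLA library 2 (0.0675), and cholesterol synthesis without Ctrl1 library 2 (0.0746), PLA1 library 1 (0.0792), Neuron-ctrl library 1 (0.0649), Neuron-ctrl library 2 (0.0572) or Neuron-PLA library 2 (0.0652). On genes with a mean of at least 1 RPKM in each set, a test added after the data had been seen, 1208 genes passed, interferon response was called only at the preset correlation (adjusted p = 0.00874, and 0.148 with an estimated correlation), radial glia passed under both settings (0.0340 with an estimated correlation), and Notch (median -0.35, adjusted p = 0.0716) and cholesterol synthesis (0.0596) were not called. Cholesterol synthesis moved to 0.15 with median-ratio and 0.16 with upper-quartile scaling, and the unfolded protein response to -0.14 with upper-quartile scaling. With the replicate block Wnt targets (0.0570) and cholesterol synthesis (0.0643) were not called.

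The interferon and stress response lists that rose in PLA1 and did not rise as lists in Neuron-PLA were weighed against 3 explanations, with tests chosen after the data had been seen. More microglia in PLA1 was not borne out, since the microglia markers had a median change of -0.99. A trend with exon length and GC was not borne out, since the interferon list kept an adjusted p of 1.3e-16 with the trend removed. A lower transgene level in Neuron-PLA could not be judged as the reason. Mean Plaat3 RPKM was 1.52 times higher in PLA1, but whether the response depends on that level was not tested. With 17 of 23 interferon genes under 1 RPKM in the neuron set, whether they respond there was not settled. Differences in sex mix, cell population, delivery or handling between the sets stay open.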

How the results depend on the processing

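Median-ratio and upper-quartile scaling and a pseudocount of 0.1 kept every count of changed genes within 1.5 times its value. The other counts moved as follows, and where construction does not explain a move (fewer samples, more genes tested, a fold floor), the cause was not tested. For the knockdown, 0 genes became 5 in the fit of 12 libraries and 1 with the replicate block, and 2 lists became 0 with an estimated correlation, with fry, with the block and with the exon length and GC trend removed. For the first set, 3438 genes became 1177 with no filter and 1101 against a fold of 1.2, and 18 lists became 0 with an estimated correlation. For the neuron set, 98 genes became 0 with no filter, 164 at 5 CPM or more, 242 in limma-voom, 9 against a fold of 1.2, 54 with the block and 474 in the fit of 12 libraries, and 17 lists became 0 with an estimated correlation and 8 with fry. For the slope, 5828 genes became 1 against a fold of 1.2 per embryonic day. Over the 7 days between the first and last stage that is a much larger change than 1.2-fold in all. Of its lists, 13 became 0 with an estimated correlation and 20 with fry. For the interaction, 1367 genes became 761 with no filter and 567 against a fold of 1.2, and 17 lists became 4 with an estimated correlation. The interaction value of Ifi44, -2.45, turned to 1.62 in limma-voom, and the cause was not tested.

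Leaving out 1 library left a group of the 2-group comparisons and of the interaction with a lone sample, assumed to vary like the other groups, and left 5 stages for the slope. The ranges were 0 to 0 genes and 1 to 12 lists for the knockdown, 1575 to 3294 genes and 15 to 18 lists for the first set, 7 to 163 genes and 11 to 16 lists for the neuron set, 2537 to 5485 genes and 13 to 16 lists for the slope, and 636 to 1218 genes and 13 to 19 lists for the interaction. Correlations ranged from -0.324 to 0.273 (knockdown and first set), -0.170 to 0.0555 (knockdown and neuron set), 0.129 to 0.191 (both overexpression sets), and with the slope from -0.460 to 0.426 (knockdown), -0.512 to -0.419 (first set) and 0.0629 to 0.147 (neuron set). The knockdown values turned sign at 0.273 (first set) without scramble library 1 and at 0.0555 (neuron set) and 0.426 (slope) without scramble library 2, and the slope value, close to 0, also at 0.0508 without Pex7sh library 1 and 0.00159 without day 11.

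Replicate numbers gave 2 pairs per comparison, and deviations of the same number correlated at 0.010, 0.099 and 0.047, so no pairing was established. With the block the first set had 4297 genes and 18 lists, the neuron set 17 lists, and the interaction 1438 genes and 15 lists. Count models with other normalisations and a fit of 12 libraries on counts, planned for deposited raw counts, were not run, and the recovered reads were tested with limma-voom only. Depth limits low genes such as Pex7, with 109 to 270 reads per library.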

Other observations

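Sex-linked genes differed between libraries. At embryonic day 16 Ddx3y was 0 and Xist 43.5 RPKM, and at day 18 Xist was 0.0523 RPKM. Both brain sets held Xist together with Y-linked genes. Eif2s3y stood at 4.78 and 4.04 RPKM in Ctrl1, 1.18 and 1.26 in PLA1, 4.82 and 7.71 in Neuron-ctrl and 10.6 and 12.0 in Neuron-PLA. Xist stood at 5.26 and 4.94 RPKM in Ctrl1, 8.52 and 9.46 in PLA1, 5.83 and 6.51 in Neuron-ctrl and 5.11 and 4.29 in Neuron-PLA. The sex mix was therefore confounded with treatment in both sets.

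Other cell-type lists differed between the scramble libraries. Cajal-Retzius markers were lower in scramble library 1 for all 8 (median -0.54), choroid plexus markers for all 5 (median -1.35), and oligodendrocyte lineage markers were higher for 8 of 9 (median 0.82). After the knockdown itself, mitochondrially encoded mRNAs had a median of 0.03 and a mean of -0.15, without a call.

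Over the stages, 26 lists were not called, with adjusted p from 0.0985 (PLAAT turnover and upper-layer markers) to 0.989 (fatty acid synthesis). Between them lay complex I (0.638), complexes II to V (0.701), peroxisomal enzymes (0.701), mitochondrial biogenesis (0.692), tricarboxylic acid cycle (0.208), glycolysis (0.652), cholesterol synthesis (0.544), integrated stress response (0.811), unfolded protein response (0.336), antioxidant genes (0.238), p53 targets (0.638), interferon response (0.364), Wnt targets (0.206), immediate early genes (0.323), deep-layer markers (0.228), oligodendrocyte lineage (0.209), interneurons (0.112), Cajal-Retzius cells (0.701), endothelium (0.238), pericytes (0.206) and choroid plexus (0.714).

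Cell-cycle and progenitor genes rose and neuronal genes fell in PLA1, and the tests of explanations were chosen after the data had been seen. A lower share of neurons as the only change was not borne out, since the median change of microglia markers minus that of radial glia markers was -1.33. A mix of cells in which several types changed was not tested and stays open. A trend with exon length and GC was not borne out, since the correlation with the developmental slope was -0.515 with the trend removed. For a state earlier on the developmental course, 89.8% of the genes called in both went against their course. That share restates the pattern that prompted the test, and a changed mix of cells could give it too. It therefore decides nothing, and an earlier state stays a hypothesis. An earlier state was not borne out as the source of the interferon genes, whose median slope of 0.00464 per day (SD 0.0584, 23 genes) compares with -0.209 needed over 7 days.

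By correlation across genes, the scramble libraries differed more from each other than libraries of different groups did. These tests were also chosen after the data had been seen. Counting error was not borne out, with a chi-square per degree of freedom of 18.9, against 2.47 in the Pex7sh pair. An exchanged label was not borne out, since the lowest bound of Pex7 in the scramble libraries was 1.04 RPKM and the highest Pex7sh value 0.669 RPKM. A trend with exon length and GC accounted for 0.789% of the variance. The difference between the scramble libraries correlated at -0.562 with the slope across genes. That value restates the shift of cell-cycle and neuronal genes and could also come from a different mix of cells. Cultures at different points of the developmental course therefore stay a hypothesis.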
